A study of Gallus gallus with 20 samples.

How the data were processed

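Lenses were dissected from chicken (Gallus gallus) embryos at embryonic day 4.5, and per the labels about 44 lenses went into each of 3 pools. Chromatin was profiled with CUT&RUN, in which an antibody directs a nuclease to cut and release the DNA around its target in isolated nuclei. Each reaction received 100000 nuclei. The series held 20 libraries: 3 each for trimethylated histone H3 lysine 4 (H3K4me3), trimethylated histone H3 lysine 27 (H3K27me3), EZH2, SUZ12, JARID2 and AEBP2, and 2 for non-specific IgG. EZH2 and SUZ12 are core subunits of Polycomb repressive complex 2 (PRC2), the enzyme that methylates H3K27, and JARID2 and AEBP2 are accessory subunits. Antibodies were diluted 1 in 25 for AEBP2, 1 in 50 for JARID2, both marks and IgG, and 1 in 100 for EZH2 and SUZ12.

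The submitters' processing notes list Trim Galore 0.6.4, Bowtie2 2.4.1, MACS2 2.2.7.1 and the genome build GRCg7b. Whether libraries were pooled before peak calling and whether IgG served as the control is not given in the sources used here. The files used were 6 peak lists, 1 per antibody. The fold of each deposited peak is a ratio over the peak caller's background, and the significance used is the deposited −log10 q-value, adjusted within the list by the authors' peak caller. The deposited score of each peak is 10 times that value, and neither it nor the summit offset entered a result. The smallest −log10 q was about 1.30 in each list, which is the value of a q limit of 0.05. A fold belongs to its own peak and list, and it was used only to describe, rank or filter peaks within that list. No IgG signal was used here, so no background level stands beside the values.

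Peaks on the assembled chromosomes were taken as regions, since no intervals in a list overlapped. Genes came from the RefSeq table of GRCg7b: 17839 protein-coding genes, of which 3539 carry only a LOC identifier. The table gives no strand. The promoter window that had been chosen before the data were examined was therefore replaced by windows of 1 kb on both sides of both gene ends, and a gene counted as marked when a region overlapped either window by at least 1 bp. Such a window can hold a peak of a neighbouring gene or of the 3′ end. Chromosome lengths were taken as the largest coordinate among peaks and genes. CpG islands and motifs were not analysed here, because no genome sequence was used.

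Shares of regions were compared with 1000 circular shifts of a list along each chromosome, two-sided, for which 0.002 is the smallest p that can be reached. For regions away from gene ends, shifted regions that landed within 5 kb of an end were left out. Genes were compared with two-sided Fisher exact tests. Both were adjusted by the Benjamini-Hochberg method within each family. Intervals are 95% intervals from resampling blocks of 5 Mb 1000 times, except exact binomial (Clopper-Pearson) intervals for shares of gene lists. H3K27me3 and H3K4me3 regions were stitched across gaps of up to 3 kb for domain widths. Odds ratios of alternatives had 0.5 added to each cell only where a cell was 0, directions were read from the counts, and alternatives of the shift tests used 200 shifts. With 1 list per antibody there are no values per library: every p compares positions or genes within these lists, neighbouring genes are not independent, and no difference was set against the spread between libraries. Read depth per library is unknown and antibody dilutions differed, so the lengths of the lists cannot be compared as amounts of binding.

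Gene lists were written before the data were examined: 12 lists tested as 1 family of 84 tests, and 7 lists of markers of other cell types tested as a family of 49. Of their 450 gene names, 416 matched a symbol of the table exactly. Named genes are members of these lists, at most about 8 per list and state in order of fold, genes with an end in the 10 widest domains of each mark, and the 5 genes with the highest fold at a gene end per antibody. Lens fiber genes and lens transcription factors are reported by state. Some genes that these rules pick are not reported here, and counts include them. Genes without a symbol were counted, not named. Alternatives covered the window, a stricter q limit, lists of equal size (the 11079 strongest peaks of each list), the overlap that counts as shared, stitching, all sequences and the background of the gene lists. Genes whose ends adjoin can share 1 peak.

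The tests were tried on simulated data with fixed seeds. In 200 lists of 5000 regions with no planted overlap with H3K27me3, 3.5% of shift tests, run there with fewer shifts, gave a p under 0.05, and with 20% of regions planted inside H3K27me3 all 20 lists did. In gene lists of 30 genes, 2.5% of 200 Fisher tests passed with nothing planted, and 96% passed with a mark on 60% of the list against 26% of other genes. Simulated regions were placed independently at random, and simulated marks were drawn independently for each gene. The runs therefore do not show how often the tests pass without cause when regions or genes are clustered. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.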

Results

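CUT&RUN peak lists of 2 histone marks and 4 PRC2 members were compared in the embryonic day 4.5 chicken lens. The H3K4me3 list held 11079 regions covering 13.0 Mb, and the H3K27me3 list held 22875 regions covering 36.7 Mb. Among PRC2 members, the EZH2 list held 25935 regions, SUZ12 54487, JARID2 48093 and AEBP2 168110. Median widths were 1021 bp for H3K4me3, 622 bp for H3K27me3, 377 bp for EZH2, 277 bp for SUZ12, 253 bp for JARID2 and 249 bp for AEBP2. Peaks with a −log10 q of at least 5 made up 95.1% of the H3K4me3 list, 54.2% of SUZ12, 43.6% of JARID2 and 44.5% of AEBP2. Read depth was unknown, and 3 libraries per antibody were represented by 1 list without replicate values.

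The lists were first placed relative to genes. H3K4me3, a mark of active and poised promoters, lay at the ends of protein-coding genes in 77.2% of its regions (95% interval 76.2 to 78.3), against 11.7% after shifting, a ratio of 6.6. EZH2 followed with 39.5% and a ratio of 4.36, SUZ12 with 24.1% and 3.04, JARID2 with 18.3% and 2.32, and H3K27me3 with 21.4% and 1.94. AEBP2 lay at gene ends in 4.63% of its regions, below the 5.58% of shifted lists. Each of these 6 shares differed from its shifts (permutation p = 0.002, the smallest the shifts can give, adjusted p = 0.002). The AEBP2 difference was lost with peaks of a −log10 q of at least 5, where the ratio was 1.02, and with windows of 500 bp, where it was 0.953. With whole genes in place of their ends the ratio was 1.51 for H3K4me3, 1.21 for EZH2, 1.22 for SUZ12, 1.1 for JARID2 and, in the opposite direction, 0.947 for H3K27me3.

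Among the genes with the highest H3K4me3 fold at an end were RPL37, which encodes a ribosomal protein, at 222, MEX3A at 214, and the neighbours OGT and TAF1 at 212. For H3K27me3 they were DCST2 at 129, COL14A1 and CBLN3 at 122, EPHB1, an ephrin receptor gene, at 120, and HOXB3 at 110, a value shared with HOXB5 to HOXB8. EZH2 reached 330 at ZIC5, a zinc finger transcription factor gene, and 291 at EVX2 and at HOXD10 to HOXD13. Among the highest JARID2 folds were LBX2 with 73.3, ZIC5 with 72 and the neighbours DLX5 and DLX6 with 70.1. SUZ12 was highest at MED18 with 40.7, CLVS1 with 40.2, SDAD1 with 31 and the neighbours CDC16 and RASA3 with 25.9, and AEBP2 at NKPD1 with 41.4, KLF5 with 22.5, BRSK1 with 20.1, GABRG3 with 20 and ESR1, an estrogen receptor gene, with 18.3. Of the genes named here for H3K4me3 all had that mark alone, and those for EZH2 had H3K27me3 alone.

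PRC2 members were next compared with their product mark. EZH2 regions lay in H3K27me3 in 36.1% of cases (34.3 to 37.7), 5.75 times the shifted share, and JARID2 regions in 20.4%, at a ratio of 3.75. SUZ12 reached 13.4% and 2.42, and AEBP2 4.37% and 1.20. Overlap with H3K4me3 was 33.1% for EZH2 at a ratio of 12.5, 19.8% for SUZ12 at 9.18, 9.56% for JARID2 at 4.55 and 2.26% for AEBP2 at 1.68. All 8 shares exceeded their shifts (permutation adjusted p = 0.002, the smallest the shifts can give). Regions more than 5 kb from every end of a protein-coding gene were compared with shifted regions that also landed more than 5 kb away. Regions at ends of non-coding genes were not left out. The 8 shares exceeded their shifts there too (largest permutation adjusted p = 0.004). The ratios in H3K27me3 were 8.06 for EZH2, 2.43 for SUZ12, 3.53 for JARID2 and 1.13 for AEBP2, and those in H3K4me3 25.8, 14.9, 6.26 and 1.65. Few shifted regions met H3K4me3 there, 0.302% for EZH2, so these ratios rest on small shares. At equal list size the H3K27me3 ratio was 9.44 for EZH2, 6.83 for JARID2, 2.95 for SUZ12 and 1.49 for AEBP2. The H3K4me3 ratio was then 9.77, 3.73, 11.8 and 1.21 in the same order. For JARID2 and AEBP2 the H3K27me3 ratio was thus the higher at equal size, unlike with the full lists.

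Strong and weak peaks of each mark were compared. Of the 2287 H3K27me3 peaks with the highest fold, 90.5% overlapped EZH2, 80.5% JARID2, 64.1% SUZ12 and 57.3% AEBP2. Of the 2288 with the lowest fold, the shares were 24.1%, 16.7%, 16.4% and 13.2%. Of the 1107 strongest H3K4me3 peaks, 78% overlapped EZH2, 50.9% JARID2, 93.7% SUZ12 and 42.1% AEBP2, and of the 1108 weakest 58.3%, 29.2%, 54.1% and 18.3%. A wider peak overlaps any list more often by its size, and these shares were neither matched on width nor compared with shifts. Of the 2595 strongest EZH2 peaks, 67.9% lay in H3K27me3 alone and 5.09% in H3K4me3 alone. Of the 5449 strongest SUZ12 peaks these shares were 11.7% and 27.3%, and 55.4% lay in neither mark. Of the 4810 strongest JARID2 peaks they were 40.3% and 3.28%, and of the 16871 strongest AEBP2 peaks 94% lay in neither mark. Over all peaks of a list, the shares in H3K27me3 alone were 28.9% for EZH2, 10.6% for SUZ12 and 17.6% for JARID2. Those in H3K4me3 alone were 26%, 17% and 6.79% in the same order. In neither mark lay 37.9% of all EZH2, 69.6% of all SUZ12, 72.8% of all JARID2 and 93.8% of all AEBP2 peaks. Of the strongest JARID2 peaks 49.6% lay in neither mark, and of the strongest EZH2 peaks 1.85%.

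Overlap in bp of each pair of lists exceeded that of shifted lists for all 15 pairs (permutation adjusted p = 0.002, the smallest the shifts can give). The ratio of the Jaccard index to its shifts was 22.2 for H3K4me3 and SUZ12, 18.7 for H3K4me3 and EZH2, 16.5 for EZH2 and JARID2, 14.6 for H3K27me3 and EZH2, and 13.6 for EZH2 and SUZ12. Pairs with AEBP2 had ratios of 1.32 with H3K27me3 to 2.77 with EZH2, and at equal list size of 1.54 with H3K4me3 to 5.2 with SUZ12. The 2 histone marks overlapped at a ratio of 1.89. Shifts do not keep the position relative to gene ends, where both marks lay more often than their shifts. The Jaccard index was not compared away from ends. Among genes these marks occurred together less often than independent marks would, with an odds ratio of 0.54 (below). With shared regions counted at an overlap of 50% of the smaller region, the ratio was 9.79 for H3K4me3 and SUZ12, 5.4 for H3K27me3 and EZH2 and 6.26 for EZH2 and JARID2. The Jaccard ratio of EZH2 and JARID2 was 40.9 at equal list size, against 16.5 with the full lists.

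Regions of EZH2 that overlapped SUZ12, here called core regions, numbered 11286. H3K4me3 was present at 64.9% of them (63.5 to 66.2) and H3K27me3 at 32.7% (31.3 to 34). EZH2 regions without SUZ12 had H3K4me3 less often, at 8.69% (7.65 to 9.85), and H3K27me3 more often, at 38.7% (36.4 to 40.9). JARID2 overlapped 41.3% of core regions (40.2 to 42.5) and AEBP2 36% (33.8 to 38.4), against 18.8% and 22.3% of EZH2 regions without SUZ12. Core regions in H3K27me3 alone had JARID2 in 61.1% of cases, and those in H3K4me3 alone in 32.3%, with intervals that did not overlap. Of all JARID2 regions 13.8% lay in the core, and of all AEBP2 regions 2.8%. Inside the core 62.7% of JARID2 regions overlapped H3K27me3, against 13.6% outside it, and for AEBP2 the shares were 43.8% and 3.24%. The shares with H3K4me3 inside and outside the core were 48% and 3.42% for JARID2 and 58.1% and 0.647% for AEBP2. A wider region overlaps any list more often by its size, and these shares were neither matched on width nor tested against shifts. At equal list size the core share with AEBP2 was 8.9%, and 29.6% of JARID2 regions in the core overlapped H3K4me3.

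Genes were then sorted by the marks at their ends. H3K4me3 alone marked 8077 genes (45.3%), H3K27me3 alone 2505 (14%), both marks 2132 (12%) and neither mark 5125 (28.7%). Genes with only a LOC identifier made up 47.5% of those with neither mark. Both marks occurred together less often than the 2654 genes that independent marks would give, with an odds ratio of 0.54 (0.465 to 0.639, Fisher exact p = 8.57e-72). The marks lay at the same end in 1757 of the 2132 genes, and at 1566 of them an H3K4me3 region at an end overlapped an H3K27me3 region.

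EZH2 was found at 96.7% of genes with both marks, 78.5% of genes with H3K27me3 alone (75.5 to 81.2), 75.7% with H3K4me3 alone (73.4 to 78.0) and 8.64% with neither. Its median fold was 9.86 at genes with H3K27me3 alone and 3.12 at genes with H3K4me3 alone. SUZ12 was found at 89.7% of genes with H3K4me3 alone (87.8 to 91.5), 88.1% with both (86.4 to 89.7) and 54.7% with H3K27me3 alone. The EZH2 intervals for H3K27me3 alone and H3K4me3 alone overlapped, as did the SUZ12 intervals for H3K4me3 alone and both. The Fisher tests below do not allow for neighbouring genes. At genes with H3K4me3 alone, both marks and H3K27me3 alone, JARID2 shares were 43%, 78.1% and 67.6%, and AEBP2 shares 39.2%, 50.6% and 45.8%. Against genes with H3K4me3 alone, genes with H3K27me3 alone had odds ratios of 1.17 for EZH2 (Fisher exact adjusted p = 0.00494), 0.139 for SUZ12 (adjusted p = 4.82e-295), 2.77 for JARID2 (adjusted p = 8.86e-104) and 1.31 for AEBP2 (adjusted p = 7.85e-09). At equal list size these were 7.53 for EZH2, 0.44 for SUZ12, 8.51 for JARID2 and 3.67 for AEBP2. Genes with both marks had odds ratios of 9.31, 0.849, 4.72 and 1.59, of which that of SUZ12 had the largest Fisher exact adjusted p, 0.033, and turned above 1 with windows of 2.5 kb, lists of equal size and whole genes. The other odds ratios at these genes were 13.8 for EZH2, 8.58 for JARID2 and 3.58 for AEBP2 at equal list size.

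**Figure D1:**
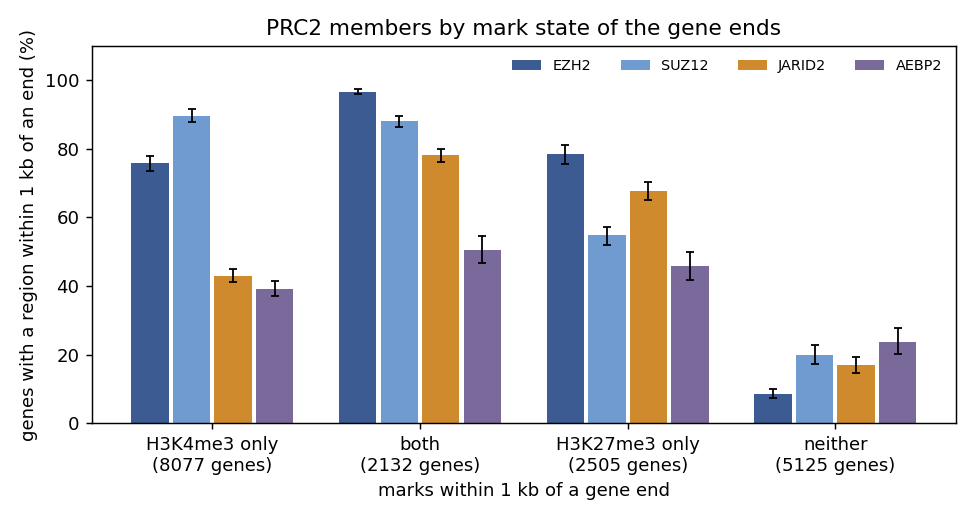
Percent of protein-coding genes with a region of each PRC2 member within 1 kb of an end, by the marks at the gene ends; bars give the share and error bars the 95% interval over resampled blocks of 5 Mb. SUZ12 falls from 89.7% at genes with H3K4me3 alone to 54.7% at genes with H3K27me3 alone, and JARID2 goes from 43% to 67.6%.

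Lens genes were taken first among the gene lists. Of 23 lens fiber structural genes, 16 had H3K4me3 alone, among them the crystallin genes CRYAA, CRYAB, CRYBA1, CRYBA4, CRYBB1, ASL1 and ASL, the beaded filament genes BFSP1 and BFSP2, the membrane protein genes MIP, LIM2 and GJA3, and GRIFIN, TDRD7 and CAPRIN2. The highest H3K4me3 folds in this group were 36.6 at MIP and 35.7 at BFSP2, and CRYAA, which encodes a small heat shock protein of the lens, had 3.61. CRYBA2 had both marks, CRYBB2 H3K27me3 alone, and CRYBB3, CRYGN, CRYGS, LGSN and DNASE2B neither. The share with H3K4me3, 73.9% against 57.2% of other genes, did not pass the test (Fisher exact adjusted p = 0.254). EZH2 was present at 6 of the 23 genes, 26.1% (10.2 to 48.4) against 59.4% of other genes (Fisher exact adjusted p = 0.00799).

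Among 29 lens transcription factor genes, 18 had H3K4me3 alone: PAX6, SOX1, SOX2, SOX3, MAF, MAFA, PROX1, FOXE3, PITX3, SIX3, EYA2, DACH1, MAB21L1, HES1, ID1, ID3, ETV1 and ETV5. The highest H3K4me3 folds were 134 at SIX3, 105 at MAB21L1 and 104 at SOX1, and PAX6, a regulator of eye formation, had 70.2. TFAP2A, MEIS1, MEIS2 and HEY1 were among those with both marks. SIX6, TFAP2B, GATA3 and EYA1 were among those with H3K27me3 alone, with EZH2 folds from 36.8 at GATA3 to 133 at SIX6, and HSF4 had neither mark. The share with H3K4me3, 79.3%, missed the threshold (Fisher exact adjusted p = 0.0589), and it passed with windows of 2.5 kb, with a −log10 q of at least 5 and with whole genes. SUZ12 at 26 of 29 genes passed it (Fisher exact adjusted p = 0.0107), but not at equal list size or with only genes that have a symbol as background. Of 27 lens epithelium and growth factor receptor genes, 23 had H3K4me3 (Fisher exact adjusted p = 0.0103), among them the growth factor receptor genes FGFR3 with a fold of 128, IGF1R and FGFR1 and the WNT receptor gene FZD1 with 108. That difference was lost against only genes with a symbol, where the odds ratio was 2.92. CDH1, DLL1 and BMPR1B had H3K27me3 alone, and FGFR2 neither mark. ITGA6 counted as having both marks with an H3K27me3 fold of 38.4, the same value as at the adjoining genes DLX1 and DLX2.

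**Figure D2:**
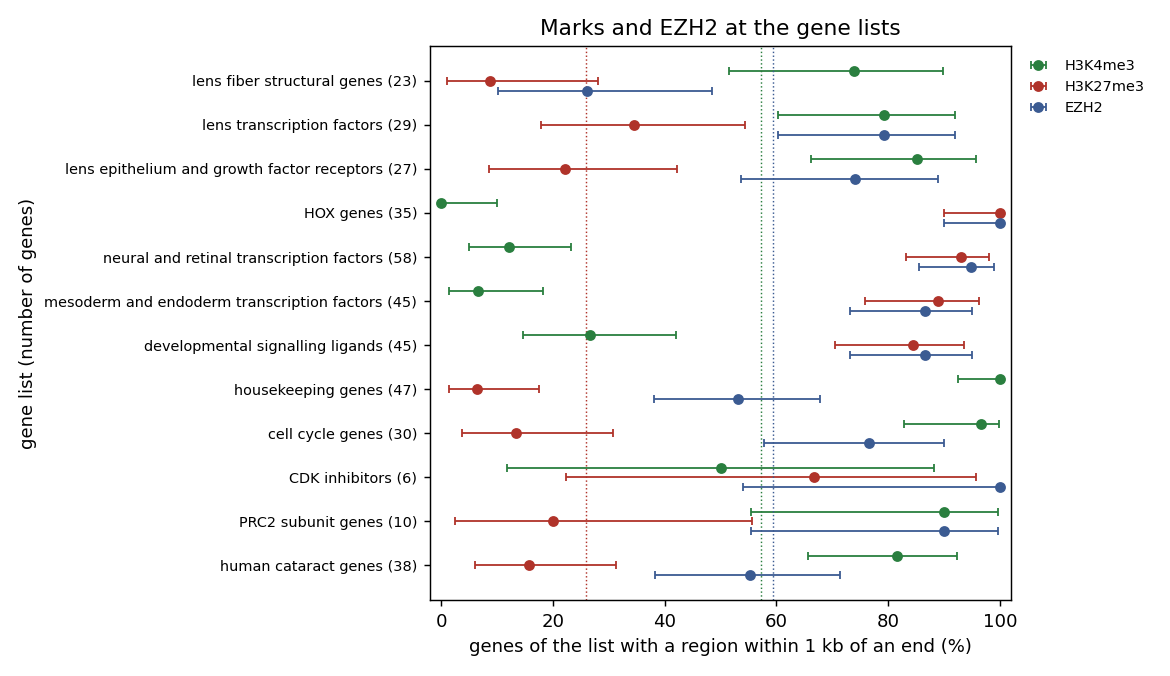
Percent of the genes of each list with H3K4me3, H3K27me3 or EZH2 within 1 kb of an end; points give the share, bars the exact binomial 95% interval and dotted lines the share in other genes. All 35 HOX genes have H3K27me3 and EZH2 and 0 have H3K4me3, while 47 of 47 housekeeping genes have H3K4me3.

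Developmental regulators of other lineages were taken next. All 35 matched HOX genes, the positional regulators of the body axis, had H3K27me3 alone, with EZH2 and JARID2 at all 35, SUZ12 at 29 and AEBP2 at 17 (Fisher exact adjusted p for H3K27me3 = 1.27e-19). These genes lie in 4 clusters and are not independent. Of 58 neural and retinal transcription factor genes, 54 had H3K27me3 (93.1% against 25.8% of other genes, Fisher exact adjusted p = 2.23e-25), led by PAX3 with a fold of 88.9, BHLHE22, ISL1, NKX2-2, EMX2 and OLIG3. OTX2, RAX, DLX2 and LMX1B were among those with both marks, LHX2 and HMX1 had H3K4me3 alone, and ATOH7 and SOX10 had neither. JARID2 was at 56 of these 58 genes (Fisher exact adjusted p = 3.87e-17). Of 45 mesoderm and endoderm transcription factor genes, 40 had H3K27me3 (Fisher exact adjusted p = 2.78e-17), led by SHOX with 101, GATA5, TBX5, TCF21, MYOG and LBX1, while WT1 had H3K4me3 alone. SUZ12 was at 38 of these 45 genes (Fisher exact adjusted p = 0.0146), a difference that 5 of 7 alternatives did not keep past the threshold. Of 45 signalling ligand genes, 38 had H3K27me3 (Fisher exact adjusted p = 5.21e-15), led by WNT2 with 73.5, FGF18, WNT1, FGF3 and DLL4. Both marks were at 11 ligand genes, among them WNT2B, WNT5A, WNT7A, WNT5B, PDGFA and BMP2. TGFB2 was the ligand gene with H3K4me3 alone, at a fold of 43. AEBP2 was at 30 of the 45 ligand genes, 66.7% against 37% (Fisher exact adjusted p = 0.000351), and did not pass at a −log10 q of at least 5 or at equal list size.

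Housekeeping genes had H3K4me3 in 47 of 47 cases and H3K27me3 in 3, LDHB, PSMA1 and PSMC1 (Fisher exact adjusted p = 5.49e-11 for H3K4me3 and 0.00485 for H3K27me3). SUZ12 was at 45 of these 47 genes, 95.7% against 64.4% of other genes (Fisher exact adjusted p = 4.06e-06), so a higher SUZ12 share was not particular to the lists of regulators. Of 30 cell cycle genes 29 had H3K4me3 (Fisher exact adjusted p = 1.16e-05), and CCND2, CDK6, TOP2A and BUB1 also had H3K27me3. The cyclin-dependent kinase inhibitor genes CDKN1B, with an H3K4me3 fold of 61.1, and CDKN1C had H3K4me3 alone, CDKN2C had both marks, and CDKN1A, CDKN2A and CDKN2B had H3K27me3 alone, with no test of the 6 genes past the threshold. H3K27me3 at these genes passed with windows of 2.5 kb, at an odds ratio of 11.4, and JARID2 at equal list size, at 12.3. Genes of PRC2 itself had H3K4me3 at 9 of 10, with both marks at AEBP2 and PHF19 and neither mark at RBBP7, a share that did not pass the test (Fisher exact adjusted p = 0.12). Of 38 human cataract genes, which share 24 genes with the lens lists above, 31 had H3K4me3 (Fisher exact adjusted p = 0.00959), a difference lost against only genes with a symbol. Over the 84 tests of the 12 lists, 20 shares were higher and 6 lower than in other genes, and none of the 12 tests of both marks passed. The smallest Fisher exact adjusted p among these, 0.0524, was that of HOX genes and of ligands, which went in opposite directions. Both marks were at 0 of 35 HOX genes and at 24.4% of ligand genes, against 12% of other genes. The HOX test passed with windows of 2.5 kb, with whole genes and against only genes with a symbol, and the ligand test with windows of 500 bp.

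Markers of other cell types that a dissected lens could hold were counted in the same way. H3K4me3 was at 0 of 9 endothelial genes and at 1 of 11 blood genes, LMO2 (Fisher exact adjusted p = 0.0224 for each). Of 13 periocular mesenchyme genes 9 had H3K27me3 (Fisher exact adjusted p = 0.0224), and 5 of these, FOXC2, TWIST1, PRRX1, PRRX2 and COL1A1, also had H3K4me3. Tests of the 8 neural retina and 8 muscle genes for H3K27me3, with 6 marked genes each, gave a Fisher exact adjusted p of 0.0511; all 8 retina genes and 4 of these muscle genes also stand in the transcription factor lists above. In the pigment epithelium and melanocyte list 3 of 8 genes had H3K4me3, PMEL, RLBP1 and MITF, and in the surface and corneal ectoderm list 2 of 5, GRHL2 and GRHL3, and these 2 lists had no test past the threshold. H3K27me3 was at 4 of 9 endothelial genes, 2 of 11 blood genes, 1 of 8 pigment epithelium and melanocyte genes and 2 of 5 ectoderm genes, none past the threshold (smallest Fisher exact adjusted p = 0.674).

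Stitching gave 499 H3K27me3 domains of 20 kb or wider. The widest, of 260 kb, covered ends of HOXB1 to HOXB8, HOXB13 and SKAP1 on chromosome 27 from 3330714 to 3590539 (GRCg7b). EZH2 covered 62.6% of the length of this domain, JARID2 39.4%, SUZ12 6.19% and AEBP2 2.12%. The next were a domain of 208 kb at BMP2, which encodes a bone morphogenetic protein, 179 kb at HOXC8 to HOXC13, and 172 kb at KY and EPHB1. Others of the first 10 lay at PAX2, at NKX2-1, NKX2-8 and PAX9, at COL27A1, at LHX3, GPSM1 and QSOX2, and at RNLS. EZH2 covered 69.1% of the HOXC domain, 40.1% of that at NKX2-1, 19.6% at LHX3, 5.32% at EPHB1, 5.19% at PAX2, 3.17% at BMP2, 3.11% at COL27A1 and 0.631% at RNLS. All 4 members were present more often in domains of 20 kb or wider than in narrower ones: JARID2 in 91.8% and 45.0%, AEBP2 in 88% and 45.9%, SUZ12 in 86.6% and 43.1% and EZH2 in 84.6% and 54.6%. A wide domain overlaps any list more often by its size, and these shares were not compared with shifts.

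With the same stitching, the widest H3K4me3 domain, of 24.1 kb, lay at TUBA1A and LMBR1L, and the second, of 21.4 kb, at SIX3. PAX6 ranked sixth with 16.9 kb on chromosome 5 from 5402228 to 5419143. The remaining wide domains lay at RTKN, INO80B, WBP1, MOGS, CCDC142 and TTC31, at SLC2A1, which encodes a glucose transporter, at MLLT10 and SKIDA1, at SOHO1 and HMX1, at DGUOK and TET3, and at BAHCC1 and SLC38A10, with 1 domain of 16.3 kb at no coding gene end. These widths and ranks depend on the stitching gap. There were 284 H3K27me3 domains of 20 kb or wider at 1 kb and 832 at 10 kb, and the widest H3K4me3 domain had 16.7 kb at 1 kb and 103 kb at 10 kb. Without stitching, PAX6 had the widest H3K4me3 peak, of 12.2 kb, and SIX3 one of 3.63 kb.

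**Figure D3:**
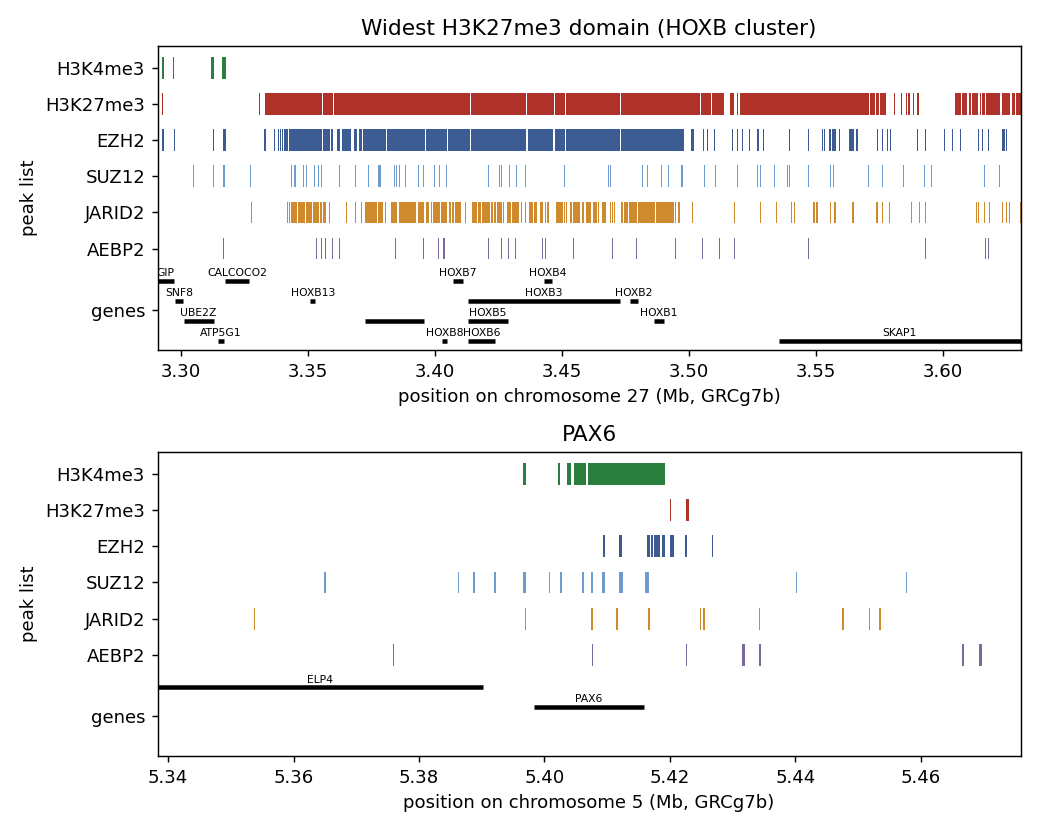
Peaks of the 6 lists and protein-coding genes at the HOXB cluster on chromosome 27 and at PAX6 on chromosome 5, by position in Mb on GRCg7b; each coloured block is a peak drawn from start to end and black bars are genes. H3K27me3 forms a domain of 260 kb over the HOXB genes, and H3K4me3 one of 16.9 kb over PAX6.

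Peak density differed between long and short chromosomes. On the 8 chromosomes of 30 Mb or longer, AEBP2 peaks were 1.9 times as dense as on shorter chromosomes (95% interval 1.57 to 2.38). The same ratio was 0.393 for H3K4me3 (0.33 to 0.47), 0.423 for H3K27me3, 0.464 for EZH2, 0.5 for SUZ12 and 0.527 for JARID2 (0.474 to 0.597). Within windows of like gene count the ratios lay closer to 1, at 1.25 for AEBP2 (1.04 to 1.55), 0.831 for H3K4me3, 0.601 for H3K27me3, 0.752 for EZH2, 0.779 for SUZ12 and 0.797 for JARID2. These comparisons were added after the lists had been seen.

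**Figure D4:**
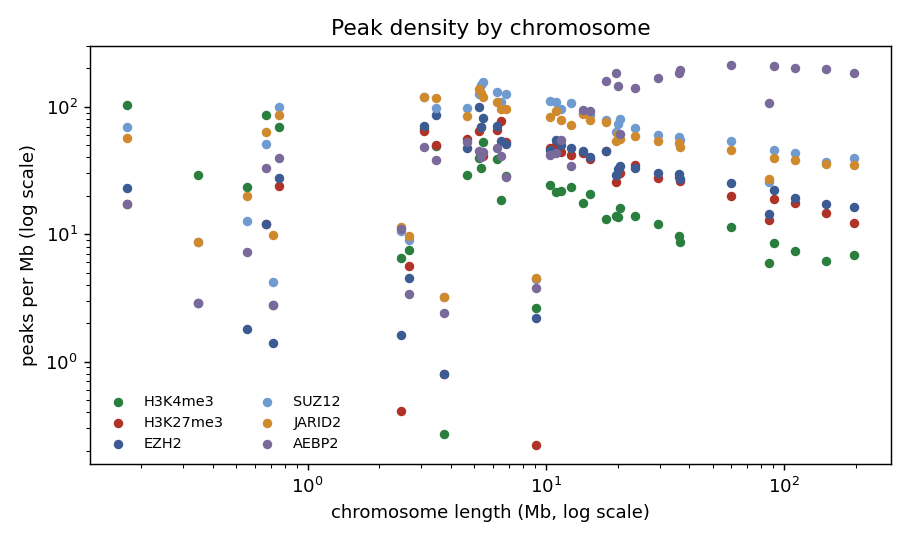
Peaks per Mb (log scale) against chromosome length in Mb (log scale) for the 6 lists; each point is a chromosome and an antibody, and densities of 0 are not drawn. AEBP2 has 183 peaks per Mb on chromosome 1, the longest, where H3K4me3 has 6.89 and JARID2 35.2.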

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

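The test of open chromatin was chosen after its result had been seen, the comparison at equal list size after the data had been seen, and the test of neighbouring H3K27me3 before. The 4 PRC2 members differed in how their presence changed from genes with H3K4me3 alone to genes with H3K27me3 alone, which is what singled these values out. The change was 2.76 percentage points for EZH2, -35 for SUZ12, 24.6 for JARID2 and 6.57 for AEBP2. EZH2 minus SUZ12 was 37.7 points (95% interval 34.6 to 41.3), EZH2 minus JARID2 -21.8 (-24.7 to -19.1) and EZH2 minus AEBP2 -3.8 (-7.16 to -0.697). SUZ12 minus JARID2 was -59.6 points (-63.3 to -55.9), SUZ12 minus AEBP2 -41.5 (-46.1 to -37) and JARID2 minus AEBP2 18 (14.6 to 21.3). The intervals resample blocks of the genome, not libraries, and the antibodies differ in list length and in dilution. Differences between members cannot be told apart from differences between antibodies. At equal list size EZH2 minus JARID2 turned to 12.1 points (8.67 to 15.3) and EZH2 minus AEBP2 to 42 (39.1 to 45). That setting changes the strength of the peaks and the genes in each state along with the length, and which of these turned the order was not tested. The other 4 differences kept their direction there, with SUZ12 below each of the others.

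EZH2 at 75.7% and SUZ12 at 89.7% of genes with H3K4me3 but no H3K27me3 formed the pattern to weigh. Spread from a neighbouring H3K27me3 region as the whole cause is argued against, since 27.1% (24.9 to 29.1) of those genes with EZH2 had H3K27me3 within 10 kb of an end, under the 50% set in advance, against 20% of those without EZH2. For SUZ12 the shares were 24.9% with it and 29.8% without. Capture of open chromatin whatever the antibody remains open. AEBP2 too was more frequent at genes with H3K4me3 alone than at genes with neither mark, with an odds ratio of 2.07 (1.71 to 2.54). The ratio was 3.7 for JARID2 (3.16 to 4.4), 33 for EZH2 and 35.3 for SUZ12. AEBP2 and JARID2 are themselves PRC2 subunits, so ratios above 1 could come from binding as well as from capture, and they cannot decide. A comparison with IgG, which could separate capture from binding, was not run, and binding of PRC2 at these genes also stays open.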

How the results depend on the processing

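Alternatives with whole genes, a matched or symbol-only background, both marks at the same end, strata of gene density, regions away from gene ends, equal list size for PRC2 members by state and the differences between them, all alternatives for lens fiber genes within H3K4me3 genes, and all for H3K4me3 widths were chosen after seeing the data. Of 304 alternatives to the 76 main results, 250 kept the direction and the side of the threshold or, without a test, stayed within a limit for their kind of value. That limit was wide for counts. Genes with both marks, 2132 in the main setting, counted as kept at 1569 with equal list size and at 2980 with windows of 2.5 kb. Their 200 shifts can give a permutation p of 0.00995 at the smallest. Of 588 alternatives to the 84 gene list tests, 503 kept both, 11 were no longer past the threshold, 32 newly passed it and 42 turned direction. The causes of the changes were not tested. No paired analysis was possible because each antibody has 1 list without values per library, so no replicate could be left out either. CpG islands, motifs and their control windows, the CpG-matched background and CpG strata were not run, since they need a genome sequence. Unknown depth limits every count of peaks.

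The odds ratio of both marks lay between 0.444 and 0.705 over its alternatives, and that of EZH2 at lens fiber genes among H3K4me3 genes between 0.00967 and 0.0832. With a −log10 q of at least 5, the lists held 29517 SUZ12, 20969 JARID2 and 74792 AEBP2 regions. Stitching across 1 kb gave 284 and across 10 kb 832 H3K27me3 domains of 20 kb or wider. At gene ends, the AEBP2 ratio was 0.953 with windows of 500 bp and 1.02 with the stricter q limit, neither past the threshold, and the H3K27me3 ratio turned to 0.947 with whole genes. The odds ratio of SUZ12 at genes with both marks turned to 1.04 with windows of 2.5 kb, 1.06 at equal list size and 1.54 with whole genes. At equal list size EZH2 minus JARID2 turned to 12.1 points and EZH2 minus AEBP2 to 42. The median H3K4me3 width was 3.19 kb over lens transcription factors without stitching, and 7.47 kb over lens fiber and 4.35 kb over housekeeping genes with a gap of 10 kb.

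With the stricter q limit, the core overlapped JARID2 in 34%, AEBP2 in 27.9%, H3K27me3 in 30.3% and H3K4me3 in 70.9% of regions. JARID2 then lay outside the core in 80.1%, with H3K27me3 at 65.9% inside and 20.3% outside and H3K4me3 at 46.8% inside and 6.0% outside. AEBP2 lay outside in 96.5%, with H3K27me3 at 39% inside and H3K4me3 at 64.6% inside and 1.05% outside. At equal list size, the core overlapped JARID2 in 30.3%, AEBP2 in 8.9% and H3K27me3 in 40.9%. JARID2 then lay outside in 89.8%, with H3K27me3 at 85.3% inside and 25.4% outside and H3K4me3 at 29.6% inside and 6.73% outside. AEBP2 lay outside in 98.3%, with H3K27me3 at 57.1% inside and H3K4me3 at 52.4% inside and 0.808% outside. With an overlap of 50% of the smaller region, the core overlapped JARID2 in 39.2% and H3K27me3 in 31.4%. JARID2 then lay outside in 87.7%, with H3K27me3 at 64.1% inside and 13.2% outside and H3K4me3 at 44.9% inside and 3.77% outside. AEBP2 lay outside in 97.4%, with H3K27me3 at 3.13% outside and H3K4me3 at 56.2% inside and 0.703% outside. With stitched H3K27me3, the mark was at 14.4% of JARID2 and 3.41% of AEBP2 regions outside the core.

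None of the 20 gene list results that turned direction had passed the threshold, and 1 passed it after turning, SUZ12 at cataract genes at equal list size, with an odds ratio of 0.199. Other odds ratios that turned at equal list size were, for lens fiber genes, 0.757 for SUZ12 and 0.689 for AEBP2, and for AEBP2 0.549 at lens transcription factors, 0.589 at receptors, 0.955 at HOX genes and 0.531 at cell cycle genes. Cell cycle genes also turned to 0.553 for SUZ12, 0.438 for JARID2 and 0.74 for both marks, and ligands to 1.03 for SUZ12. AEBP2 was then at 0 CDK inhibitor and 0 PRC2 genes, where the odds ratios, 2.49 and 1.54, come from the added 0.5 and do not show the direction. With windows of 2.5 kb, AEBP2 turned to 0.802 at lens transcription factors and 0.987 at CDK inhibitors, both marks to 0.767 at cell cycle genes and 1.43 at receptors, H3K4me3 to 1.29 at CDK inhibitors, JARID2 to 1.17 at PRC2 genes and SUZ12 to 1.003 at ligands. With windows of 500 bp, AEBP2 turned to 0.69 at lens fiber genes and 0.804 at mesoderm and endoderm factors, and JARID2 to 1.02 at cataract genes. With the stricter q limit, AEBP2 turned to 0.668 at lens fiber genes, 1.21 at housekeeping genes and 0.635 at CDK inhibitors, JARID2 to 0.668 at receptors and 1.003 at PRC2 genes, both marks to 0.967 at cell cycle genes and SUZ12 to 1.18 at ligands. With whole genes, AEBP2 turned to 0.67 at lens fiber genes, SUZ12 to 1.99 at ligands, H3K4me3 to 1.25 at CDK inhibitors, JARID2 to 1.24 at cataract genes and both marks to 1.46 at receptors. Against a background matched on gene density and chromosome length, AEBP2 turned to 0.705 at lens transcription factors, 0.805 at receptors and 1.06 at housekeeping genes. Against only genes with a symbol, SUZ12 turned to 0.998 and AEBP2 to 0.904 at lens fiber genes, AEBP2 to 0.86 at lens transcription factors and both marks to 0.978 at cell cycle genes.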

Other observations

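The families, the widths, the comparison within H3K4me3 genes and that of AEBP2 density were chosen after the data had been seen, while the test of each explanation was fixed before its result was seen. Among 20 gene families picked by symbol, marks differed. H3K27me3 was at 23 of 23 glutamate receptor genes (Fisher exact adjusted p = 6.69e-13 over 60 tests), 63 of 82 potassium channel genes (adjusted p = 4.61e-20) and 25 of 37 FOX genes (adjusted p = 1.01e-06), against about 26% of other genes. Of these FOX genes 7 stand in gene lists, and 19 of the other 30 had H3K27me3 (Fisher exact adjusted p = 7.5e-05 over 60 tests without listed genes). H3K4me3 was at 68 of 68 ribosomal protein genes (Fisher exact adjusted p = 1e-15) and 31 of 31 proteasome genes (adjusted p = 2.84e-07), of which 17 and 4 stand in gene lists, and at all 51 and 27 others. It was at 1 of 17 keratin genes (Fisher exact adjusted p = 6.32e-05) and 1 of 22 chemokine and receptor genes (adjusted p = 1.54e-06), and the H3K27me3 shares of these families, 23.5% and 22.7%, did not pass the test (adjusted p = 1 for each). Both marks together were at 7 of 17 semaphorin genes (Fisher exact adjusted p = 0.00615).

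H3K4me3 domains were wide at lens genes. The median stitched width was 6.82 kb over 23 lens transcription factor genes with the mark and 2.96 kb over 17 lens fiber genes, against 1.4 kb over all 10209 marked genes. Without stitching the medians were 3.19 kb and 2.37 kb, against 1.24 kb. The central 95% of 10000 random lists of marked genes, not matched on fold, reached 1.95 kb for the size of the transcription factor list and 2.04 kb for that of the fiber list. Both medians lay above the upper limit without stitching too, and with gaps of 1 kb and 10 kb. With stitching, SIX3 had 21.4 kb, PAX6 16.9 kb, SOX1 14.1 kb, MAF 12.7 kb, PITX3 12.1 kb and the fiber gap junction gene GJA3 11.1 kb, and their single peaks were narrower, with 3.63 kb at SIX3, 12.2 kb at PAX6, 3.0 kb at SOX1, 6.32 kb at MAF, 1.71 kb at PITX3 and 3.79 kb at GJA3. Housekeeping genes, with 2.27 kb, lay above their limit of 1.75 kb too, while 7 neural and retinal factor genes had a median of 0.862 kb.

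Lens fiber genes with H3K4me3 had EZH2 at 4 of 17, 23.5% against 80.2% of other H3K4me3 genes (Fisher exact adjusted p = 2.84e-05 over 36 tests). These 4 were CRYBA2, CRYBB1, MIP and TDRD7, with EZH2 folds from 1.3 at CRYBB1 to 2.1 at MIP. Weaker H3K4me3 peaks are argued against, since random lists matched on H3K4me3 fold had EZH2 at 80.4% on average and at 58.8% or more in the central 95%. Fewer neighbouring genes are argued against too, with 78.9% in lists matched on gene density and chromosome length. Housekeeping genes with H3K4me3 were low as well, at 53.2% (Fisher exact adjusted p = 0.000507), and lens transcription factors, at 78.3%, did not differ (adjusted p = 0.994). Sequence composition was not tested, so a biological difference at fiber genes is only a hypothesis.

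AEBP2 peaks were 1.9 times as dense on long as on short chromosomes (1.57 to 2.38), while the other 5 lists had ratios from 0.393 to 0.527. Calls near the threshold are argued against, since the ratio was 2.24 (1.68 to 3.14) among the strongest 11079 AEBP2 peaks. Fewer genes on long chromosomes as the whole cause stays open. Within windows of like gene count the AEBP2 ratio fell to 1.25 (1.04 to 1.55), and the other 5 lists moved to 0.601 to 0.831. Gene count thus took up much of the difference. The short chromosomes include W, which has about as many genes per Mb as chromosome 1. W has 3.75 AEBP2 peaks per Mb, against 183 on chromosome 1. Windows so poor in peaks can raise the matched ratio, which was not computed without them, so a lower limit of 1.04 cannot decide. Sequence composition and background signal were not tested and stay open, and no biological explanation was tested.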
